A study of Homo sapiens with 3 samples.

How the data were processed

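Human neural organoids were grown from H9, an established human embryonic stem cell line, by 3 protocols aimed at dorsal forebrain, ventral forebrain and whole cerebral tissue. Per the labels' protocols, each organoid was dissociated on its own with papain on day 50 and its cells were stained with a TotalSeq-B hashtag, an antibody against surface proteins that carries a DNA barcode. The cells of 4 organoids of a protocol were then mixed in equal proportions, aiming for more than 2500 cells per organoid, and made into 1 library with 10x Genomics Chromium 3' chemistry and feature barcoding. The data are therefore 3 libraries from 12 organoids, with 1 library per protocol.

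The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, and UMI counts of the hashtags, per the file headers, which name Cell Ranger 3.1.0. Per the submitters' processing notes the genome build was hg19, and Seurat 4.1.1 is named there without a role. The gene annotation is not given in the sources used here, so no coordinates are reported and each gene is identified by the symbol and Ensembl identifier of the deposited feature list. That list has 32738 genes and 5 hashtags. Of the genes, 186 share a symbol with another and were kept apart by identifier. It was checked on the values that the matrices hold whole numbers without normalisation and that the deposited barcodes start at about 500 UMIs.

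Cells were kept with at least 500 detected genes and at most 20% mitochondrial UMIs, which left 10001 dorsal, 3069 ventral and 7597 cerebral cells. Hashtag counts were scaled by a centred log ratio, and each cell was given to 1 hashtag, to several or to none with HTODemux of Seurat 5.3.0 at a positive quantile of 0.99. Hashtags 0251 to 0254 stand for organoids 1 to 4 of a protocol, and these numbers pair nothing between protocols. The last listed hashtag was not used. Cells with several hashtags or none were left out. Scrublet, run within Scanpy 1.11.5, called 2.91% of dorsal cells doublets but 0.163% of ventral and 0.0263% of cerebral cells, too few for a working threshold in the latter libraries. The number of undetected doublets within 1 organoid, from those seen across hashtags, was expected to be 191, 40.7 and 138 in the 3 libraries.

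All assigned cells were clustered together with Scanpy 1.11.5 and leidenalg 0.10.2. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were used without batch correction, and a graph of 15 neighbours was split with the Leiden method at resolution 0.8. A cluster was named from marker lists when the mean log2 fold of a list over the other cells reached 0.5, after adding 20 CPM (counts scaled to a common library size), with at least 3 raised markers and no conflict among its top 10 genes. Clusters with over 25% Scrublet calls stayed unnamed. These naming thresholds were set after the clusters were seen. Names carry the ending "-like" because they rest on RNA alone. Many clusters came almost entirely from 1 library, and such a cluster may be set apart by the library as well as by the cell type.

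The organoid was the replicate, with n = 4 per protocol. Counts were summed over the cells of each organoid and every pair of protocols was fitted on its own with the edgeR 4.0.16 quasi-likelihood test under R 4.3.3, after filterByExpr and TMM scaling. A gene was called changed with a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The same fit was run within broad classes of cells, for organoids with at least 20 cells of the class. Values are CPM as mean ± SD over organoids, and log2 fold changes carry an approximate standard error (SE). It is the absolute log2 fold change divided by the square root of the F statistic of the test. Where 1 group has few counts of a gene this SE can be too small, and it then understates the counting error. Because each protocol is 1 culture in 1 library, the p-values measure differences against the spread between organoids of a culture, and protocol and library cannot be told apart in any comparison.

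There were 31 gene lists, 23 of cell type markers and 8 of pathways, tested when at least 3 members passed the filter. The test was camera of limma 3.58.1 with a preset correlation of 0.01 between genes, run again with an estimated correlation, and adjusted over all lists and the 3 comparisons. The directional test of fry was also run and decided no call. For each list the number of changed members is given, and it was counted again with p-values adjusted over the list alone. Where a group had no count of a gene, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, either the counts alone or the ratio with its 95% counting interval is given. These bounds and intervals cover counting error only.

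Shares of cells per organoid were compared with an exact two-sided permutation test over the 70 arrangements of 4 against 4 organoids, which can give no p below 0.0286. Shares were adjusted over classes and comparisons. Marker shares count cells with at least 2 markers of a list after thinning every cell to 3000 UMIs, and leave out shallower cells. The spread between organoids was measured as the distance of each organoid from the mean log2 CPM of its protocol, after drawing 570 cells of 3000 UMIs from every organoid. The log2 CPM of this distance used a prior count of 2. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used for these steps, and matplotlib 3.10.9 for the plots.

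Genes are named in the text by a fixed rule. It takes, from each list, up to 2 changed members with the largest change, and from all changed genes with a mean log2 CPM of at least 5 and groups that did not overlap, the 6 largest rises and the 6 largest falls, or 4 of each within a class, without mitochondrial, ribosomal and sex-linked genes. Other list members may be named where their list is described. The filters, the tests and thresholds for genes, lists, shares and spread, the gene lists and the naming rule for genes were chosen before the data were examined. The fits within cortical glutamatergic and GABAergic neuron-like cells and the shares of cells with cortical or GABAergic markers were added after the clusters were seen.

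The gene fit was tested on simulated data made from these libraries with 200 changed genes per comparison. Here a call needed an adjusted p under 0.05 in the right direction and no minimum fold change, so the figures do not describe the full rule for changed genes. Of the genes changed 1.5-fold the fit recovered 50% in dorsal against ventral, 38% in dorsal against cerebral and 54% in ventral against cerebral organoids. At 2-fold the figures were 74%, 74% and 68%, and at 8-fold 94%, 94% and 98%. Among unchanged genes 14, 6 and 20 had an adjusted p under 0.05. Alternatives were DESeq2 1.42.0 and its size factors, library size scaling, no filter on low counts, 1 model of all 12 organoids, leaving out each organoid, other hashtag and cell filters, removal of the cells with the highest Scrublet scores, equal cells and UMIs, other Leiden resolutions, thinning before clustering and other marker thresholds. Scaling by library size moved the median log2 fold change of all genes by 0.11 in dorsal against ventral organoids, and fold changes are reported relative to the TMM scale.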

Results

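Single-cell RNA profiles were collected from dorsal forebrain, ventral forebrain and cerebral organoids at day 50, with 4 organoids of each protocol told apart by hashtags within 1 library. The deposited libraries held 102775800 gene UMIs in 10168 dorsal barcodes, 29134072 in 3162 ventral barcodes and 96388177 in 7773 cerebral barcodes. After filtering, cells had a median of 9193 UMIs and 3225 genes in dorsal, 8449 UMIs and 2775 genes in ventral, and 11886 UMIs and 3641 genes in cerebral organoids. The median mitochondrial share of UMIs per cell was 2.90% ± 0.102 in ventral organoids, against 1.39% ± 0.116 in dorsal and 1.56% ± 0.115 in cerebral ones (mean and SD over 4 organoids), so every comparison with ventral organoids also sets apart this sign of cell quality. A single hashtag was assigned to 7892 dorsal cells, 78.9% of the filtered cells with an exact Clopper-Pearson 95% interval of 78.1% to 79.7%. It was assigned to 2706 ventral cells, 88.2% with an interval of 87.0% to 89.3%, and to 5610 cerebral cells, 73.8% with an interval of 72.8% to 74.8%. Cells without a clear hashtag made up 15.4%, 7.82% and 20.9% of the 3 libraries and cells with several hashtags 5.67%, 3.94% and 5.23%. The mixing aimed for more than 2500 cells per organoid, and 1674 to 2151 cells were assigned to each dorsal, 589 to 737 to each ventral and 1081 to 1761 to each cerebral organoid. The UMIs summed per organoid ranged from 16242420 to 23292354 in dorsal, from 5594708 to 7107777 in ventral and from 16680240 to 23522769 in cerebral organoids, so genes at low levels were measured least precisely in ventral organoids.

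Neurons of different kinds made up the organoids of the 3 protocols. Cortical glutamatergic neuron-like cells were 35.4% ± 18.6 of the assigned cells in dorsal and 37.5% ± 7.52 in cerebral organoids (SD, n = 4). None were found among 2706 ventral cells, which allows a share of up to 0.111% by counting error alone. GABAergic neuron-like cells were 61.7% ± 3.23 of ventral, 19.0% ± 27.2 of dorsal and 0.0897% ± 0.106 of cerebral cells. Choroid plexus-like cells (10.4% ± 5.39), retina and pigment cell-like cells (6.64% ± 2.73) and mesenchyme-like cells (2.11% ± 0.747) were found in cerebral organoids. In dorsal and ventral organoids the choroid plexus-like share was 0.0349% and 0.0798%. None of the 7892 dorsal and 2706 ventral cells fell in the other 2 classes, which allows shares of up to 0.0380% and 0.111%. These limits, like that for ventral cortical neuron-like cells, take cells as independent. They do not cover the spread between organoids or the cells of unnamed clusters. Progenitor-like cells, with radial glia or cycling markers, made up 26.3% ± 1.90 of dorsal, 24.4% ± 3.799 of ventral and 19.8% ± 0.971 of cerebral cells.

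Of 21 tests of these shares, 15 gave the smallest p that the exact two-sided permutation test of 4 against 4 organoids allows, 0.0286, with an adjusted p of 0.04. When 1 organoid was left out, 0 shares passed without any 1 ventral organoid or without dorsal organoid 1, 3 or 4, and 14 passed without any other organoid. Without dorsal organoid 1, 3 or 4 the lowest adjusted p of the lost calls was 0.05, equal to the threshold. Without 1 ventral organoid it was 0.0545 or more. The lost calls kept their direction and most of their size. The cortical glutamatergic difference of dorsal against ventral organoids was 30.3 to 35.7 points over these leave-outs, against 35.4 with all organoids. The GABAergic difference of ventral against cerebral organoids was 60.3 to 62.9 points without any 1 ventral organoid, against 61.6 with all. Among the 15 was the progenitor-like share of dorsal against cerebral organoids. The GABAergic share of dorsal against ventral organoids did not pass (exact p = 0.0571, adjusted p = 0.075), with an adjusted p from 0.0370 to 0.12 over its alternatives and a difference of -42.7 points that was -55.8 without dorsal organoid 2 and then passed. Against cerebral organoids the dorsal GABAergic share was higher by 18.9 points, or 5.84 without dorsal organoid 2. It passed with an adjusted p of 0.04 but not without any 1 of the cerebral organoids or without dorsal organoid 1, 3 or 4, with an adjusted p from 0.0370 to 0.212 over its alternatives. The cortical glutamatergic share did not differ detectably between dorsal and cerebral organoids (exact p = 0.857), and its difference of -2.11 points turned to 6.56 without dorsal organoid 2 and to 1.36 without cerebral organoid 1. Intermediate progenitor-like cells, the dividing precursors of cortical neurons, were 11.1% ± 5.64 of dorsal, 7.63% ± 0.512 of cerebral and 0.105% ± 0.131 of ventral cells, and the difference between dorsal and cerebral organoids was not past the threshold (exact p = 0.257). That difference of 3.45 points was 6.21 without dorsal organoid 2 and then passed, with an adjusted p of 0.0429 in a range of 0.0429 to 0.503 over its alternatives. A small class of Cajal-Retzius-like cells, the reelin-secreting neurons of the cortical surface, held 0.528% ± 0.541 of cerebral cells. It held no cell of the other protocols. At resolution 0.4 the name went to a cluster of 1279 cells from all 3 libraries, led by HSPA1A and HSPA1B. The class therefore did not stand for the same cells at each clustering setting. Cells of unnamed clusters were 8.24% of dorsal, 13.7% of ventral and 15.3% of cerebral cells.

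**Figure D1:**
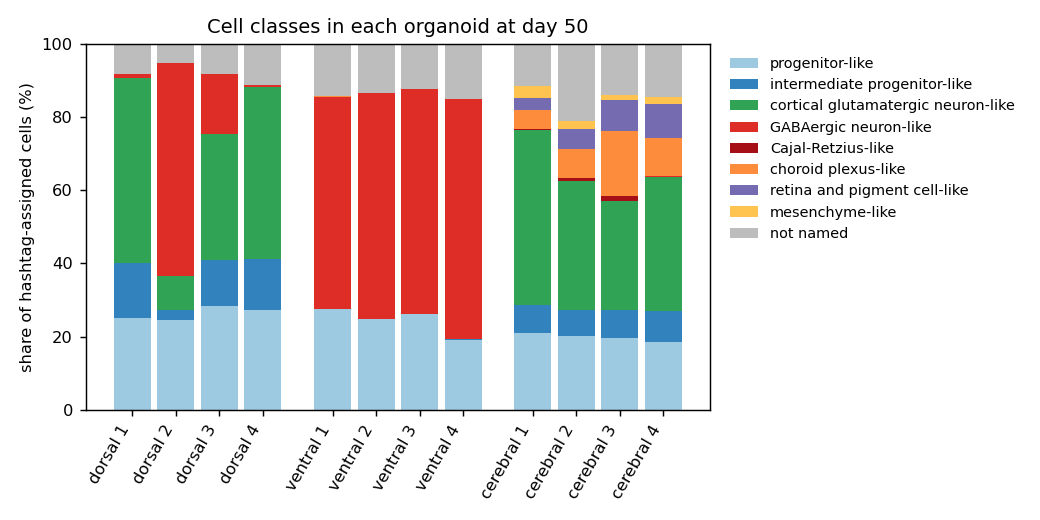
Stacked bars show the percentage of assigned cells in each class for each of the 12 organoids, grouped by protocol. Dorsal organoid 2 holds 58.2% GABAergic and 9.38% cortical glutamatergic neuron-like cells, while the ventral organoids hold 57.9% to 65.8% GABAergic neuron-like cells.

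The series set out to measure how organoids of a culture vary, and the dorsal organoids differed most in their neurons. GABAergic neuron-like cells were 58.2% of the cells of dorsal organoid 2 and 16.4% of organoid 3, against 0.873% and 0.499% of organoids 1 and 4. Cortical glutamatergic neuron-like cells moved the other way, with 9.38% in organoid 2, 34.5% in organoid 3, 50.6% in organoid 1 and 47.1% in organoid 4. The same was seen without clusters, from single cells thinned to 3000 UMIs. At least 2 GABAergic markers were found in 66.3% of the cells of dorsal organoid 2, 20.7% of organoid 3, 1.29% of organoid 1 and 1.69% of organoid 4, against 79.3% ± 3.40 in ventral and 0.125% ± 0.153 in cerebral organoids. In cells that should lack these markers, cortical glutamatergic neuron-like cells, the share was 0.770% in the dorsal library (median 10508 UMIs per cell) and 0.0490% in the cerebral library (median 11629 UMIs). GABAergic neuron-like cells had a median of 7745 UMIs in the dorsal library and 8180 in the ventral library. At least 2 cortical markers were found in 47.4% ± 23.2 of dorsal, 51.1% ± 5.95 of cerebral and 0.529% ± 0.281 of ventral cells, and the ventral value lay below the 0.722% of ventral GABAergic neuron-like cells that stand for background. The exact two-sided permutation p was 0.0286 for each pair of protocols and each marker share except cortical markers in dorsal against cerebral organoids, where it was 0.943. Without dorsal organoid 2 the GABAergic marker share of dorsal organoids exceeded that of cerebral organoids by 7.76 points instead of 22.4. The exact p of this difference rose to 0.171 without any 1 of the cerebral organoids, and that of dorsal against ventral organoids to 0.0571 without any 1 of the ventral ones, so neither call held there. The differences themselves hardly moved, at 22.3 to 22.4 points against cerebral and -58.0 to -55.4 points against ventral organoids.

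**Figure D2:**
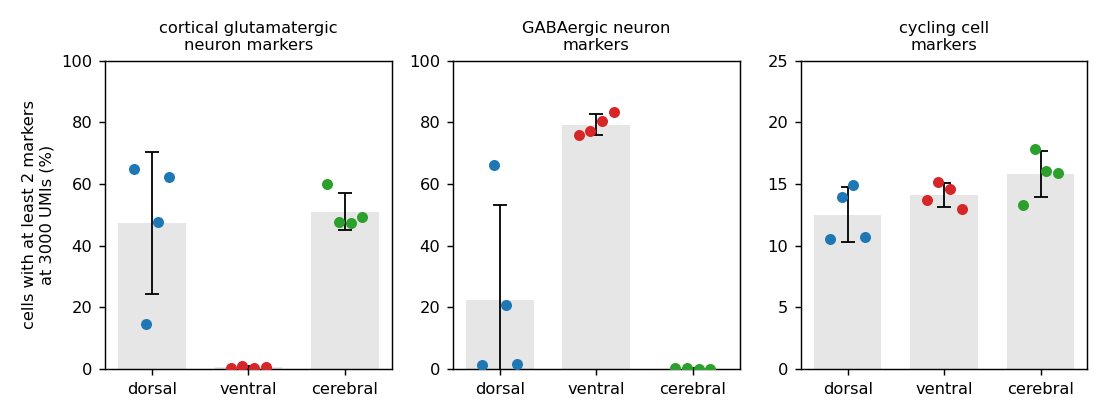
Percentage of cells with at least 2 markers of cortical glutamatergic neurons, of GABAergic neurons or of cycling cells after thinning to 3000 UMIs, with dots for organoids, bars for protocol means and error bars for the SD over 4 organoids. The dots of the dorsal organoids lie far apart for GABAergic markers, from 1.29% to 66.3%, and those of the ventral and cerebral organoids lie close together.

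Across all expressed genes, the distance of an organoid from the mean profile of its protocol was 0.351 ± 0.0706 in dorsal, 0.283 ± 0.0107 in ventral and 0.278 ± 0.0150 in cerebral organoids, in log2 CPM over 11254 genes at equal cells and UMIs. Dorsal organoid 2 lay at 0.449 and the other dorsal organoids at 0.334, 0.281 and 0.340. The exact two-sided permutation p was 0.0857 for dorsal against ventral, 0.0571 for dorsal against cerebral and 0.6 for ventral against cerebral organoids, so a difference in spread was not shown with this distance. With 1 minus the Spearman correlation as the distance, the spread was 0.0342 in dorsal, 0.0206 in ventral and 0.0251 in cerebral organoids, and ventral organoids were less spread than either of the others (exact p = 0.0286 for dorsal against ventral and for ventral against cerebral). The adjusted p was 0.0429 for both, in a range over the alternatives of 0.0286 to 0.8 and of 0.0429 to 0.914. Without thinning the direction turned, with ventral organoids more spread than cerebral ones by 0.0856 (exact p = 0.0286, adjusted p = 0.0857). The dorsal difference from ventral organoids was then -0.0119. Whether the protocols differ in spread, and in which direction, therefore depends on the measure and on thinning. Without dorsal organoid 2 the dorsal excess fell from 0.0676 to 0.0154 over ventral and from 0.0732 to 0.0210 over cerebral organoids. Without dorsal organoid 3 it was 0.0998 and 0.105, each with an exact p of 0.0286. The edgeR biological coefficient of variation at equal depth was 0.135 in dorsal, 0.0530 in ventral and 0.0809 in cerebral organoids.

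A difference in dividing cells was not shown between the 3 protocols. At least 2 cycling markers, genes of mitosis such as MKI67 and TOP2A, were found in 12.5% ± 2.25 of dorsal, 14.1% ± 0.955 of ventral and 15.8% ± 1.87 of cerebral cells (SD, n = 4), with exact two-sided permutation p of 0.286, 0.0857 and 0.171 for dorsal against ventral, dorsal against cerebral and ventral against cerebral organoids. The last was 0.0286 with at least 1 marker, and also without cerebral organoid 1. Cortical glutamatergic neuron-like cells, which do not divide, gave a background of 0.490% in the dorsal and 0.637% in the cerebral library. Without thinning, cerebral cells, which had more UMIs per cell, held cycling markers more often at 26.99% ± 3.82 against 19.9% ± 1.77 in dorsal and 19.1% ± 1.23 in ventral organoids (exact p = 0.0286 for both).

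Dorsal against ventral organoids differed in the regional programme of the forebrain. PAX6 (ENSG00000007372), a transcription factor of cortical radial glia, stood at 174 ± 28.5 CPM in dorsal and 0.609 ± 0.502 CPM in ventral organoids (SD, n = 4), a log2 fold change of 8.11 ± 0.26 (SE, edgeR adjusted p = 1.02e-07). NEUROD6 (ENSG00000164600), a factor of cortical glutamatergic neurons, had 472 ± 274 CPM in dorsal organoids and a total of 1 count in the ventral ones, from organoid 2, a ratio of 13028 with a counting interval of 2338 to 514604. In ventral organoids NKX2-1 (ENSG00000136352), which specifies the medial ganglionic eminence, stood at 203 ± 26.8 CPM against 3 counts over all dorsal organoids, a ratio of 5707 with an interval of 1952 to 27682. LHX8 (ENSG00000162624), a factor of ventral neurons including cholinergic ones, stood at 151 ± 13.1 CPM against 2 dorsal counts, a ratio of 6348 with an interval of 1756 to 52437. The edgeR test called 1391 of 14987 genes changed, 769 higher and 622 lower in dorsal organoids. With library size scaling it was 896 higher and 503 lower, and without dorsal organoid 2 it was 764 higher and 767 lower. The levels of all 4 organoids per protocol did not overlap for 39.9% of the genes, against 2.86% by chance. With equal cells and UMIs, which leaves fewer UMIs per organoid, 782 genes were called.

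All 8 tested genes of dorsal telencephalic progenitors rose in dorsal organoids. They included EMX1, which marks the cortical primordium, at 85.3 ± 51.3 CPM against no count in ventral organoids, at least 794-fold higher, and the Hedgehog repressor GLI3 at 92.7 against 9.56 CPM. The camera test gave the list an adjusted p of 1.26e-06, and an adjusted p of 0.164 with an estimated correlation. Cortical glutamatergic neuron genes rose in 8 of 9 cases, with SLA at 9.38 ± 0.58 log2 and the vesicular glutamate transporter SLC17A7 at 8.26 ± 0.92 log2 (adjusted p = 1.26e-06 for the list, adjusted p = 0.164 with an estimated correlation), and BCL11B, which cortical and striatal neurons share, was at 286 against 224 CPM. Of 7 intermediate progenitor genes 5 rose, or 6 when adjusted over the list alone, such as NHLH1 at 5.94 log2 and the proneural factor NEUROG2 at 79.2 ± 43.2 CPM against 1 count, from ventral organoid 4 (adjusted p = 0.00119 for the list, adjusted p = 0.342 with an estimated correlation). Radial glia genes split. HES1, a Notch effector, the glial fatty acid binding protein FABP7, the glutamate transporter SLC1A3 and PTPRZ1 rose, the last by 2.19 ± 0.14 log2 to 589 ± 9.80 CPM, NES fell by 1.67, and the other 5 of 10 did not pass (adjusted p = 0.0214 for the list, adjusted p = 0.557 with an estimated correlation).

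Ventral telencephalic progenitor genes fell in dorsal organoids in 6 of 7 cases (adjusted p = 2.82e-06, adjusted p = 0.164 with an estimated correlation). Among them OLIG2, which marks ventral progenitors and oligodendrocyte precursors, was at 1.04 against 26.2 CPM. SHH, the morphogen that induces ventral fate, was at 0.426 against 44.6 CPM, with a log2 fold change of -6.93 that became -7.70 without dorsal organoid 2. GABAergic neuron genes fell in 5 of 12 cases (adjusted p = 2.79e-05, adjusted p = 0.349 with an estimated correlation). Among them were LHX8, GAD1, the interneuron factor LHX6 at -10.67 ± 0.21 log2, and the neuropeptide SST at -3.92 ± 0.97 log2, or -5.28 without dorsal organoid 2, -3.17 with a stricter hashtag rule and -7.06 with equal cells and UMIs. DLX5, a factor of GABAergic precursors, did not pass, at 84.3 ± 124 CPM in dorsal and 155 CPM in ventral organoids (adjusted p = 0.458). SFTA3, a neighbour of NKX2-1, was at 0.114 against 71.6 ± 3.16 CPM, and its log2 fold change of -9.23 became -10.00 without dorsal organoid 1. OLIG1, a partner of OLIG2, was at -5.24 log2 and at -6.58 without dorsal organoid 2.

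Among other lists, 2 of 3 oligodendrocyte precursor genes fell, PCDH15 by 1.84 and PDGFRA by 3.16 log2, the latter by 1.99 without ventral organoid 2 (adjusted p = 0.0496 for the list, adjusted p = 0.342 with an estimated correlation). In the synapse list 1 of 10 genes rose, the glutamate receptor GRIA2, at 275 ± 33.0 against 118 CPM and 1.10 ± 0.09 log2, or 0.98 with a stricter hashtag rule (adjusted p = 0.0265 for the list, adjusted p = 0.51 with an estimated correlation). The remaining lists did not pass camera. In the Hedgehog response list 3 of 6 genes rose, all of them SHH co-receptors (list adjusted p = 0.0743). GAS1 was at 4.95 ± 0.24 log2, BOC at 2.97 ± 0.31 and CDON at 2.48. There was 1 further fall when adjusted over the list alone. A rise of co-receptors does not by itself show a higher Hedgehog response in dorsal organoids. In the BMP response ID2 rose by 2.77 ± 0.20 log2, BAMBI rose and ID3 fell, of 5 tested (adjusted p = 0.156). Of 10 immediate-early and heat shock genes, FOS, FOSB, EGR1 and JUNB rose (adjusted p = 0.149), and JUNB, at 2.14 log2, was at 1.41 without dorsal organoid 2, and lost its call at 1.13 with a stricter hashtag rule and without ventral organoid 1 at 2.13 or ventral organoid 3 at 2.14. In the diencephalic list LHX9 and SLC17A6 rose and POU4F1 and GBX2 fell, the last to 0.0451 against 21.2 CPM, of 5 tested (adjusted p = 0.694). Of 4 Cajal-Retzius genes CALB2 and RELN rose (adjusted p = 0.571), RELN at 1.18 log2 and 0.92 without dorsal organoid 2. Of 5 astroglia genes, SLC1A2 and S100B rose and SPARCL1 fell by 3.28 (adjusted p = 0.667); SPARCL1 was at -4.90 without dorsal organoid 2 and lost its call at -2.10 with a stricter hashtag rule, and S100B, at 1.72, was not called without any 1 of 5 organoids, at 1.29 without dorsal organoid 2, and was at 2.65 without ventral organoid 2.

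WNT response genes went both ways, LEF1 at 3.83 log2, or 3.198 without dorsal organoid 3, and SP5 at -3.32, of 6 tested (adjusted p = 0.871). Of 4 epithelium genes EPCAM rose at 1.29 log2, or 0.99 without dorsal organoid 2 (adjusted p = 0.571), and of 12 glycolysis and hypoxia genes CA9, a hypoxia-induced carbonic anhydrase, rose by 3.48 log2 (adjusted p = 0.794). The edgeR test, like DESeq2, called 0 members of the lists for cycling cells (10 tested, list adjusted p = 0.27), neurons of any kind (8, adjusted p = 0.257), cortical hem and roof plate (4, adjusted p = 0.347), the unfolded protein response (10, adjusted p = 0.265) and cholesterol synthesis (9, adjusted p = 0.743), with 0, 5, 1, 4 and 0 members at an unadjusted p under 0.05. Fewer than 3 members could be tested for the hypothalamic, midbrain and hindbrain, choroid plexus, retina, mesenchyme, endothelium, microglia, neural crest and pluripotent lists. Counts adjusted over the list alone were the same except where another is given.

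Within progenitor-like cells the regional genes differed as in whole organoids. PAX6 was at 362 ± 41.98 CPM in dorsal and 0.812 ± 0.740 CPM in ventral progenitor-like cells (SD, n = 4), a log2 fold change of 8.68 ± 0.24 (SE, edgeR adjusted p = 3.51e-10), EMX1 was at least 191-fold higher in the dorsal cells, and OLIG2 was at -5.72 ± 0.21 log2. NKX2-1 had 2 dorsal counts against 171 ± 21.1 CPM, a ratio of 2077 with an interval of 574 to 17170. The test called 1089 genes, 669 higher and 420 lower in dorsal cells. The largest progenitor-like cluster of dorsal organoids held 1405 dorsal cells and 0 ventral ones, so class and library overlap here. Within neuron-like cells 1732 genes were called, 1076 higher and 656 lower, but with clusters at resolution 0.4 it was 692 higher and 721 lower. Neuron-like cells of dorsal organoids include cortical glutamatergic ones and those of ventral organoids are GABAergic, so this fit sets different kinds of neurons against each other. PALMD had no ventral count but was at 8.09 log2 with clusters at resolution 0.4. At that resolution the neuron-like class also held a cluster led by HSPA1A and HSPA1B, with 559 dorsal and 125 ventral cells. EMX1 was at least 336-fold higher in dorsal neuron-like cells, and LHX8 was at least 2336-fold lower.

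GABAergic neuron-like cells of dorsal and ventral organoids differed in 1562 genes, 1060 higher and 502 lower in dorsal cells, with only dorsal organoids 2 and 3 holding at least 20 such cells (2 against 4 organoids). With clusters at resolution 0.4 it was 693 higher and 538 lower. The clusters of this class separated by library, with 2 of them holding 1080 and 584 ventral cells and 0 dorsal ones, and 2 others 807 and 548 dorsal cells against 12 and 0 ventral ones. The dorsal cells had PAX6 at 224 ± 28.8 CPM against 2 ventral counts, a ratio of 1564 with an interval of 433 to 12924. GNRH1, which encodes gonadotropin-releasing hormone, was at 312 ± 245 CPM against 1.36 CPM, with a log2 fold change of 7.36 that was 2.81 with clusters at resolution 0.4 and 8.08 without ventral organoid 3. It was 8.05 without dorsal organoid 2 and 6.29 without dorsal organoid 3, each of which leaves 1 dorsal organoid that is assumed to vary like the ventral ones. NKX2-1 and LHX8 had no dorsal count and were at least 912-fold and at least 616-fold lower in the dorsal cells. MEIS2, a factor of lateral ganglionic eminence and striatal cells that was chosen after its values were seen, was at 1375 ± 1.68 CPM in dorsal and 17.98 ± 4.24 CPM in ventral cells.

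Dorsal against cerebral organoids had cortical neurons on both sides, while cerebral organoids held further tissues. TTR (ENSG00000118271), the thyroid hormone carrier made by choroid plexus, stood at 1.08 ± 0.412 CPM in dorsal and 4795 ± 2021 CPM in cerebral organoids (SD, n = 4), a log2 fold change of -12.14 ± 0.51 (SE, edgeR adjusted p = 2.87e-06). The collagen gene COL3A1 (ENSG00000168542) was at 0.0479 against 223 ± 83.8 CPM, and PMEL, which builds the fibrils of pigment granules, at 0.0659 against 206 ± 84.0 CPM. PAX6 was at 174 ± 28.5 against 156 CPM, 0.07 log2, and NEUROD6 at 472 ± 274 against 565 ± 76.0 CPM, -0.32 log2, neither past the test. In dorsal organoids GAD2 (ENSG00000136750), which makes GABA, stood at 84.2 ± 124 against 0.10 CPM, 9.46 log2, or 7.69 without dorsal organoid 2. The test called 2137 of 16513 genes changed, 490 higher and 1647 lower in dorsal organoids, and organoids of the 2 protocols did not overlap for 42.9% of genes against 2.86% by chance. With equal cells and UMIs 580 genes were called.

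Mesenchyme genes fell in dorsal organoids in 6 of 6 cases (adjusted p = 2.47e-06, adjusted p = 0.123 with an estimated correlation), with COL1A1 at -10.52 ± 0.53 log2. The growth factor gene IGF2 fell by 10.31 and the matrix gene MGP by 10.62, or by 11.42 without dorsal organoid 1. Choroid plexus genes fell in 5 of 5 (adjusted p = 6.6e-05, adjusted p = 0.168 with an estimated correlation), among them FOLR1 at 0.0678 against 19.5 CPM. Cortical hem and roof plate genes fell in 7 of 7 (adjusted p = 1.02e-05, adjusted p = 0.164 with an estimated correlation), with the morphogen BMP4 at -6.34 ± 0.52 log2, the WNT agonist RSPO3 at -4.18 and MSX1 at -3.62. Retina and pigment genes fell in 5 of 5 (adjusted p = 0.000109, adjusted p = 0.161 with an estimated correlation), including the melanin enzyme DCT at 15.2 against 430 CPM. Epithelium genes fell in 5 of 5 (adjusted p = 0.000819, adjusted p = 0.121 with an estimated correlation), with keratin KRT8 at -4.01 ± 0.24 log2. Astroglia genes fell in 6 of 7 (adjusted p = 0.00225, adjusted p = 0.168 with an estimated correlation), with the lipid carrier APOE at 5.75 against 143 CPM. No cluster was named from the astroglia or epithelium lists. All 3 tested hindbrain genes, HOXA3, HOXB2 and HOXB3, fell (adjusted p = 0.00103, adjusted p = 0.166 with an estimated correlation). HOXA3 had 1 dorsal count against 2.17 CPM, a ratio of 186 with an interval of 33.0 to 7404, HOXB2 had none and was at least 557-fold lower, and HOXB3 had 3 dorsal counts, a ratio of 169 with an interval of 57.5 to 823.

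BMP response genes fell in 5 of 7 (adjusted p = 0.000137, adjusted p = 0.161 with an estimated correlation), with ID3, a direct BMP target, at 0.599 against 121 CPM and -7.81 ± 0.37 log2, and MSX2 at -5.61. In the WNT response NKD1, NOTUM and SP5 fell, of 8 tested (adjusted p = 0.00336, adjusted p = 0.342 with an estimated correlation), SP5 at -4.06 log2, -3.42 without cerebral organoid 3 and -7.13 with a stricter hashtag rule. GABAergic genes rose in 8 of 10, or 9 when adjusted over the list alone (adjusted p = 0.00235, adjusted p = 0.557 with an estimated correlation). The homeobox genes DLX2 and DLX5 of this list were at 8.21 and 6.27 log2, or 6.48 and 4.52 without dorsal organoid 2. Of 8 neuron genes INA, a neurofilament gene, and DCX, a microtubule gene of young neurons, rose (adjusted p = 0.000108, adjusted p = 0.338 with an estimated correlation). INA was at 1.09 ± 0.13 log2 and at 0.93 with equal cells and UMIs. DCX was at 1.04 and not called without dorsal organoid 1 at 0.98, dorsal organoid 2 at 0.97 or cerebral organoid 4 at 1.00. In the synapse list 4 of 10 genes rose, among them CAMK2B, SYN1 and the sodium channel gene SCN3A (adjusted p = 0.000145, adjusted p = 0.342 with an estimated correlation), with CAMK2B at 1.13 ± 0.14 log2 and SCN3A at 1.21 ± 0.13, or 0.95 with equal cells and UMIs.

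The lists of the cortical lineage did not pass camera. The list of cortical glutamatergic genes, with 9 tested, had an adjusted p of 0.6. Of 8 dorsal progenitor genes DMRT3 and EMX2 fell, or 1 when adjusted over the list alone (adjusted p = 0.114), DMRT3 by 2.27 and EMX2 by 1.26, the latter with its call lost without any 1 of 6 organoids, at -0.95 without dorsal organoid 2. Of 10 radial glia genes HES1 fell, at 189 ± 17.3 against 626 ± 114 CPM and -1.81 ± 0.14 log2, and PTPRZ1 and SLC1A3 rose (adjusted p = 0.532), SLC1A3 at 1.16 log2 and 0.88 without dorsal organoid 2. Of 6 Cajal-Retzius genes RELN, TP73 and EBF3 fell (adjusted p = 0.347), EBF3 at -1.75 log2, which lost its call without any 1 of 6 organoids and was at -1.44 without dorsal organoid 2 and -2.76 without dorsal organoid 3. LHX9 fell and SLC17A6, a vesicular glutamate transporter, rose among 5 diencephalic genes (adjusted p = 0.349), SLC17A6 at 1.49 log2 and without its call at 1.47 and 1.41 when cerebral organoid 3 or 4 was left out. In the oligodendrocyte precursor list LHFPL3 and PCDH15 rose and PDGFRA and CSPG4 fell (adjusted p = 0.922). In the glycolysis and hypoxia list LDHA, CA9 and the glucose transporter SLC2A1 fell, of 12 (adjusted p = 0.584). LDHA (ENSG00000134333), which makes lactate, was at 34.0 ± 9.52 against 209 ± 49.2 CPM and -2.71 ± 0.23 log2, while the glycolytic enzyme PGK1 was at 744 against 530 CPM, 0.41 log2.

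Of 10 stress response genes TRIB3 and HSPA5 fell (adjusted p = 0.624), HSPA5 at -1.01 log2, with its call lost without dorsal organoid 1 at -0.97, dorsal 4 at -0.96, cerebral 3 at -0.87 or cerebral 4 at -0.90. Of 10 immediate-early and heat shock genes HSPA1A fell by 1.37, or 1.11 without a call under a stricter hashtag rule (adjusted p = 0.6), a value that its near-identical neighbour HSPA1B leaves uncertain. In the Hedgehog list PTCH1 rose, of 6 (adjusted p = 0.562), at 1.22 log2, with its call lost without dorsal organoid 2 at 0.77, dorsal 3 at 1.26, cerebral 1 at 1.06 or cerebral 4 at 1.11. In the pluripotency list L1TD1 fell and DPPA4 rose, of 4 (adjusted p = 0.931), L1TD1 at -3.65 log2 and -3.04 without cerebral organoid 2, DPPA4 at 1.203 with its call lost without any 1 of 6 organoids, at 0.76 without dorsal organoid 2. The edgeR test, like DESeq2, called 0 members of the lists for cycling cells (10 tested, adjusted p = 0.0536), intermediate progenitors (7, adjusted p = 0.278), ventral telencephalic progenitors (3, adjusted p = 0.6) and cholesterol synthesis (9, adjusted p = 0.6), with 5, 1, 0 and 1 members at an unadjusted p under 0.05. Fewer than 3 members could be tested for the hypothalamic, endothelium, microglia and neural crest lists. Counts adjusted over the list alone were the same except where another is given.

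Cortical glutamatergic neuron-like cells of dorsal and cerebral organoids differed in 851 genes, 433 higher and 418 lower in dorsal cells, but 353 higher and 392 lower with clusters at resolution 1.5. SCG2, which encodes a secretory granule protein, was at 216 ± 97.48 against 15.1 CPM and 3.77 ± 0.33 log2 (SE, n = 4, edgeR adjusted p = 2.35e-05), and at 2.66 with clusters at resolution 1.5. The upper-layer factor POU3F2 was at 3.64 ± 0.30 log2 and FSTL5 at 3.08 ± 0.29. The transcriptional repressor BCL6 was at 4.26 ± 0.57, or 2.82 at that resolution. At that resolution a cluster of 643 dorsal cells was named as other neurons and fell outside this class. Its top 10 genes included SCG2, BCL6 and FSTL5. In whole organoids SCG2 and FSTL5 were also among the largest rises, at 2.73 and 2.69 log2. The linker histone gene H1F0 was at 21.8 ± 4.31 against 144 ± 12.1 CPM and -2.89 ± 0.10 log2 and SCG5 at -2.87 ± 0.33. TTR had 1 count in these dorsal cells, from organoid 3, against 80.5 ± 26.3 CPM in cerebral ones, where it stood at 1.63% of its level in the library while 15 other genes of choroid plexus, pigment and mesenchyme cells had a median of 1.40%. The clusters of this class separated by library, with the largest holding 1625 dorsal and 3 cerebral cells and the next 107 dorsal and 1167 cerebral ones.

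Progenitor-like cells of both protocols differed in 816 genes, 506 higher and 310 lower in dorsal cells. Some of their clusters also separated by library, 1 with 1405 dorsal and 8 cerebral cells and another with 80 dorsal and 721 cerebral ones. FBXO32, a ubiquitin ligase gene, was at 110 ± 43.2 against 1.72 CPM and 5.83 ± 0.38 log2. ID3 fell by 6.96, the tubulin gene TUBA1C was at 4.83 against 197 ± 14.3 CPM and -5.41 ± 0.25 log2, and STXBP6 was at -3.53 ± 0.15. The neuropeptide gene NPY was at 4.80 log2 and at 4.16 without dorsal organoid 2. Neuron-like cells differed in 972 genes, 581 higher and 391 lower, or 432 and 409 with clusters at resolution 1.5. Those of dorsal organoids 2 and 3 include many GABAergic cells and cerebral organoids held 5 in all, so this fit mixes kinds of neurons. It had H1F0 at -2.71 ± 0.15 log2 and NFIX, a factor of late progenitors, at 69.6 ± 55.1 against 419 ± 35.9 CPM.

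Ventral against cerebral organoids differed in the most genes. GAD2 stood at 175 ± 5.79 CPM in ventral and 0.10 ± 0.0736 CPM in cerebral organoids (SD, n = 4), a log2 fold change of 10.66 ± 0.14 (SE, edgeR adjusted p = 1.08e-12). DLX2 (ENSG00000115844), which drives GABAergic fate, stood at 344 ± 29.8 against 0.25 CPM, 10.53 ± 0.17 log2. In cerebral organoids NEUROD6 stood at 565 ± 76.0 CPM against 1 ventral count, a ratio of 14718 with an interval of 2641 to 581347, and EMX1 at 103 ± 11.4 CPM against none, at least 903-fold higher. TTR had 2 ventral counts, from organoid 3, against 4795 ± 2021 CPM, and COL3A1 had none and was at least 1923-fold higher in cerebral organoids. The test called 3114 of 15481 genes changed, 1132 higher and 1982 lower in ventral organoids, and organoids of the 2 protocols did not overlap for 54.9% of genes against 2.86% by chance. With equal cells and UMIs 1412 genes were called.

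GABAergic genes rose in ventral organoids in 12 of 12 cases (adjusted p = 1.39e-10), the 1 list in the 3 comparisons that also passed with an estimated correlation (adjusted p = 0.0442). DLX5 was at 7.33 ± 0.13 log2 and GAD1 at 104 against 1.51 CPM. LHX8 had 3 cerebral counts, all from organoid 3, against 151 ± 13.1 CPM, a ratio of 3928 with an interval of 1343 to 19057. Ventral progenitor genes rose in 7 of 7 (adjusted p = 2.52e-05, adjusted p = 0.0795 with an estimated correlation), with OLIG2 at 26.2 against 0.689 CPM, OLIG1 at 9.07 log2, or 9.81 without cerebral organoid 2, and NKX2-1 at 203 ± 26.8 CPM against 3 cerebral counts, a ratio of 5297 with an interval of 1812 to 25695. Dorsal progenitor genes fell in 8 of 8 (adjusted p = 1.4e-06, adjusted p = 0.0795 with an estimated correlation), with PAX6 at 0.609 against 156 CPM. Cortical glutamatergic genes fell in 8 of 9 (adjusted p = 4.31e-05, adjusted p = 0.0795 with an estimated correlation), with FEZF2, a factor of deep-layer neurons, at 0.969 against 257 CPM. Intermediate progenitor genes fell in 6 of 7 (adjusted p = 4.12e-05, adjusted p = 0.0801 with an estimated correlation), among them NEUROG2 (ENSG00000178403) with 1 ventral count, from organoid 4, against 65.0 ± 2.89 CPM. Of 8 neuron genes DCX, INA, STMN2 and GAP43 rose (adjusted p = 0.000479, adjusted p = 0.375 with an estimated correlation), DCX at 1330 ± 132 against 475 CPM and 1.54 ± 0.09 log2.

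Genes of tissues outside the cortical lineage were again mostly higher in cerebral organoids. No cluster was named from the astroglia or epithelium lists. The astroglia genes GJA1 and APOE were among the top 10 genes of the retina and pigment cell-like cluster. SPARCL1 was among those of a choroid plexus-like cluster. Mesenchyme genes fell in ventral organoids in 6 of 6 (adjusted p = 4.32e-05, adjusted p = 0.161 with an estimated correlation), with the matrix gene DCN at 1 count, from ventral organoid 4, against 80.7 ± 36.5 CPM. Cortical hem genes fell in 7 of 7 (adjusted p = 8.48e-05, adjusted p = 0.214 with an estimated correlation), with MSX1 at -3.54. Astroglia genes fell in 6 of 7 (adjusted p = 0.000538, adjusted p = 0.161 with an estimated correlation), with the filament gene GFAP at 2 counts against 24.2 CPM. Choroid plexus genes fell in 4 of 5 (adjusted p = 0.00306, adjusted p = 0.349 with an estimated correlation), with HTR2C at 3.88 against 78.2 CPM, while OTX2 did not pass, at 23.1 against 27.6 CPM. Retina and pigment genes fell in 5 of 5 (adjusted p = 0.00196, adjusted p = 0.203 with an estimated correlation), with DCT at -9.40. Epithelium genes fell in 4 of 4 (adjusted p = 0.00684, adjusted p = 0.168 with an estimated correlation), with KRT8 at -3.94. The hindbrain genes HOXA3, HOXB2 and HOXB3 fell (adjusted p = 0.0199, adjusted p = 0.318 with an estimated correlation), HOXA3 with 2 counts against 2.17 CPM, a ratio of 29.2 with an interval of 7.97 to 243, and HOXB2 with 1 count, from ventral organoid 4, against 18.8 CPM, a ratio of 524 with an interval of 93.9 to 20702. HOXB2 was highest in cerebral organoid 3, at 37.5 CPM.

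BMP response genes fell in 6 of 7 (adjusted p = 8.48e-05, adjusted p = 0.161 with an estimated correlation), with ID1 at -3.31. MSX2 had 1 count, from ventral organoid 2, a ratio of 284 with an interval of 50.8 to 11231, and SMAD6 1 count, from ventral organoid 3, a ratio of 92.5 with an interval of 16.5 to 3668. WNT response genes fell in 5 of 8 (adjusted p = 0.0225, adjusted p = 0.354 with an estimated correlation), with the WNT effector LEF1 at -4.75 ± 0.23 log2, and NKD1 at -2.35, or -2.97 without ventral organoid 4. Of 10 immediate-early and heat shock genes EGR1, JUNB and FOSB fell (adjusted p = 0.0235, adjusted p = 0.557 with an estimated correlation), EGR1 at 42.3 against 149 CPM. The other lists did not pass camera. Of 6 Hedgehog genes 2 rose, the target PTCH1, at 1.90 ± 0.20 log2, and HHIP, and 4 fell, among them GAS1 by 5.44, BOC by 3.57 and CDON by 2.62 (list adjusted p = 0.138). Of 10 radial glia genes NES rose and HES1, SLC1A3, FABP7 and PTPRZ1 fell (adjusted p = 0.12), HES1 at 53.3 against 626 ± 114 CPM and -3.51 ± 0.18 log2. GBX2 rose and LHX9, SLC17A6 and BARHL2 fell among 6 diencephalic genes (adjusted p = 0.44), GBX2 at 6.60 ± 0.22 log2 and BARHL2 with 1 count, from ventral organoid 2, a ratio of 77.7 with an interval of 13.8 to 3081. Of 3 hypothalamic and optic genes FEZF1 rose by 3.50 log2 and RAX and SIX6 fell (adjusted p = 0.584), RAX at -6.83, or -6.04 without cerebral organoid 2, and SIX6, with no ventral count, at least 136-fold lower.

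Of 3 oligodendrocyte precursor genes PCDH15 rose at 4.26 ± 0.23 log2 and LHFPL3 at 2.89 ± 0.22 (adjusted p = 0.102), and of 5 Cajal-Retzius genes RELN fell by 2.74, CALB2 by 1.23, and EBF3 fell with 7 ventral counts (adjusted p = 0.347). In the glycolysis and hypoxia list LDHA fell by 1.90, CA9 by 6.54, SLC2A1 by 1.60 and ANKRD37 by 1.16, of 12 (adjusted p = 0.513). In the stress response list CHAC1 rose, of 10 (adjusted p = 0.951), at 1.17 log2 and 0.81 with a stricter hashtag rule, and in the synapse list SCN3A rose by 2.12 ± 0.11 log2, of 10 (adjusted p = 0.171). The edgeR test, like DESeq2, called 0 members for cycling cells (10 tested, adjusted p = 0.643) and cholesterol synthesis (9, adjusted p = 0.327), with 0 and 6 members at an unadjusted p under 0.05. Fewer than 3 members could be tested for the endothelium, microglia, neural crest and pluripotent lists. Counts adjusted over the list alone were the same for every list of this comparison.

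Within progenitor-like cells of ventral and cerebral organoids 1405 genes were called, 666 higher and 739 lower in ventral cells. Some clusters of this class separated by library here too, with 310 and 343 ventral cells and 0 cerebral ones in 2 of them, and 721, 229 and 150 cerebral cells with 2 ventral ones in 3 others. OLIG1 was at least 1140-fold higher in ventral cells, and EMX1 was at least 258-fold and NEUROG2 at least 147-fold lower. NKX2-1 stood at 171 ± 21.1 CPM against 1 cerebral count, from organoid 3, a ratio of 2949 with an interval of 528 to 116553. Within neuron-like cells 2526 genes were called, 1147 higher and 1379 lower, but 1310 higher and 1095 lower with clusters at resolution 0.4, with LHX6 at least 1601-fold higher in ventral cells. The neuregulin receptor gene ERBB4 had no cerebral count, but was at 6.41 log2 with clusters at resolution 0.4 and 6.92 at 1.5. FEZF2 had 2 ventral counts against 647 ± 67.0 CPM, a ratio of 4659 with an interval of 1290 to 38477, and was at -8.67 log2 with clusters at resolution 0.4. Neuron-like cells are GABAergic in the ventral and cortical glutamatergic in the cerebral library, so this fit sets different kinds of neurons against each other. At resolution 0.4 the neuron-like class also held a cluster led by HSPA1A and HSPA1B, with 125 ventral and 595 cerebral cells.

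**Figure D3:**
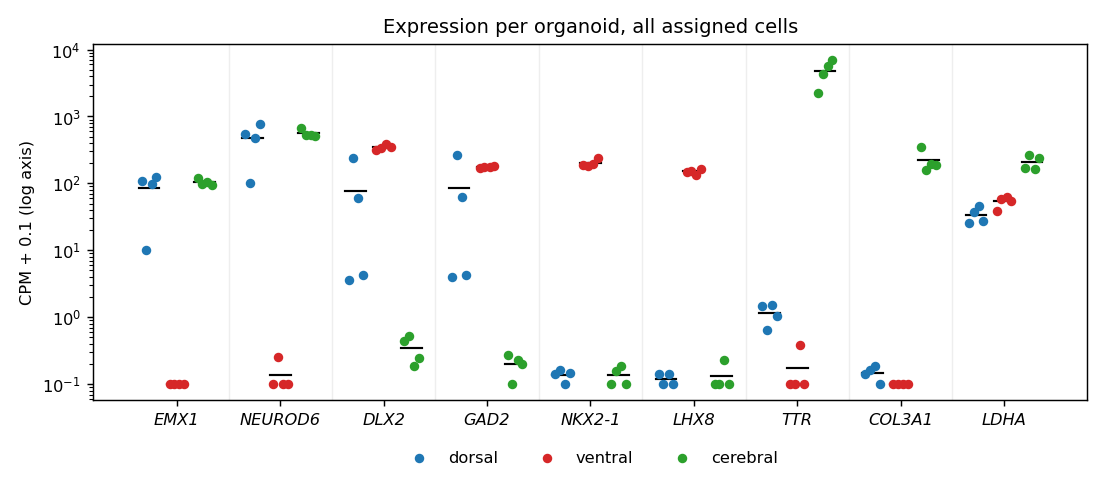
Level of 9 genes in each of the 12 organoids, in CPM plus 0.1 on a log axis, with a dot per organoid and a line at the mean of each protocol. EMX1 and NEUROD6 are near 0 in ventral organoids, NKX2-1 and LHX8 are near 0 in dorsal and cerebral organoids, and TTR and COL3A1 are high in cerebral organoids, where TTR averages 4795 CPM.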

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

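The tests for ventral cells, for doublets, for free TTR RNA and for cell make-up behind LDHA were chosen only after the results they measure were seen.

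GABAergic neuron-like cells were frequent in dorsal organoids 2 and 3 and rare in organoids 1 and 4. Cells from the ventral library or culture are argued against, because 0.0754% of the 1327 cells had a UMI of LHX6, LHX8 or NKX2-1, against 93.8% of 1676 ventral GABAergic neuron-like cells and a background of 0.0693% in dorsal cortical neuron-like cells. Doublets are argued against as the main source of these cells, because their median was 7599 UMIs against 10223.5 in cortical neuron-like cells of the same organoids. At least 2 cortical markers were held by 3.91% of 1280 such cells, against 0.722% of ventral GABAergic neuron-like cells. A low share follows in part from choosing the cells by cluster, and doublets among a part of them stay open. How many cells wrong hashtag calls gave from organoid 2 to organoid 3 cannot be decided, because the cells were assigned by the same hashtag counts. The share of the hashtag of organoid 2 was 1.23 times that of other cells in organoid 3 (bootstrap 95% interval 1.15 to 1.31). This was below the 1.5 times set beforehand for such calls, but the assignment itself limits the ratio. The 2 hashtags of other organoids gave 1.16 and 1.23. The hashtag of organoid 3 had a median share of 59.2% in these cells and 66.4% in its other cells. With a top hashtag of at least 80% the shares were 38.5% in organoid 2 and 10.3% in organoid 3, the latter 33 of 320 cells. Wrong calls for a part of the cells, small or large, stay open, and no biological explanation was tested.

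TTR, a transcript of choroid plexus, was found in cortical glutamatergic neuron-like cells of the cerebral library. Free RNA from other cells may explain this, since the level of TTR relative to the library was 1.16 times the median of 15 other genes of choroid plexus, pigment and mesenchyme cells, though those genes ranged from 0.620% to 39.3%. Doublets with choroid plexus cells cannot be told apart from it, because 43.7% of the TTR UMIs lay in the top 5% of cells against 19.7% if every UMI were equally likely to be TTR. At least 1 TTR UMI was seen in 47.1% of 2075 cells, and the level by organoid was 66.8, 71.6, 63.9 and 119.7 CPM.

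LDHA was higher in the cerebral than in the dorsal library. A different make-up of broad classes is argued against as the whole cause, because the log2 fold change was -2.13 within cortical glutamatergic neuron-like cells. The clusters of this class separated by library, so a different make-up within the class stays open. Free RNA from other cells is argued against, with 2.89 CPM expected from it against 111 CPM seen in those cells, and so is depth per cell, with -2.55 ± 0.20 log2 at equal cells and UMIs. The library rather than the protocol cannot be told apart, since each protocol has 1 library. PGK1, another glycolytic enzyme, was at 744 CPM in dorsal and 530 CPM in cerebral organoids, and the protocol stays among the open explanations, as untested.

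For the fits across genes with 4 organoids in each group, the real grouping was compared with all 35 splits of the 8 organoids into groups of 4. Every other split puts both protocols in each group, which widens the spread within groups, so few calls were likely there. The splits show that the calls follow the grouping by library. They cannot exclude chance differences between cultures or libraries, since each protocol has 1 of each. The fit within GABAergic neuron-like cells, with 2 against 4 organoids, was not split. The real split was the 1 that gave as many changed genes, with 1391, 2137 and 3114 in whole organoids against 0 in every other split. The same held within progenitor-like cells (1089, 816 and 1405 against 0), neuron-like cells (1732, 972 and 2526 against 0) and cortical glutamatergic neuron-like cells (851 against 0). For gene lists past an adjusted p of 0.05 chance is not excluded, and the splits cannot measure it. Splits that exchange 1 organoid per protocol keep a part of the protocol difference. The list p-values of each split were also adjusted together with the real ones of the other 2 comparisons. Of the 35 splits, 7 gave at least the 8 lists of dorsal against ventral organoids, 10 at least the 12 of dorsal against cerebral and 4 at least the 16 of ventral against cerebral organoids, with 9, 16 and 17 lists in the highest other split.

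Single organoids lay far from the other organoids of their protocol in 8 of 165 groups of 4 values, where 8.25 are expected by chance. Cerebral organoid 1 had cortical markers in 59.9% of cells (others 47.5% to 49.3%), NEUROD6 at 678 CPM (others 515 to 533) and DCX at 566 CPM (others 440.5 to 449.9). Cerebral organoid 3 had EMX2 at 335 CPM (others 262 to 268), HOXB3 at 10.6 CPM (others 3.74 to 4.32) and SP5 at 14.5 CPM (others 3.96 to 4.97). Dorsal organoid 2 had HSPA1A at 53.9 CPM (others 18.6 to 22.8), and ventral organoid 4 had OTX2 at 18.4 CPM (others at least 24.2). The hashtag that was listed but given to no organoid had 1102 UMIs in the dorsal, 193 in the ventral and 656 in the cerebral library, or 0.0207%, 0.0233% and 0.0157% of hashtag UMIs.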

How the results depend on the processing

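Removing the cells with the highest Scrublet scores, the fits within cortical glutamatergic and GABAergic neuron-like cells and the shares of cells with cortical or GABAergic markers were chosen only after the data were seen. The alternatives were run for the called genes that the rule names, not for every gene in the text, and no value of those genes turned its direction. Of 722 values for 39 genes in dorsal against ventral organoids, 26 lost their call, as did 44 of 1014 for 55 genes in dorsal against cerebral, 12 of 1013 for 55 genes in ventral against cerebral and 7 of 96 for 8 genes in dorsal against cerebral neuron-like cells. Depth limits the ventral library most, and genes near its counting limit are given as bounds. The cause of the changes below was not tested, except where the setting itself gives it.

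With equal cells and UMIs, which leaves fewer counts per organoid, 782 genes were called in dorsal against ventral, 580 in dorsal against cerebral and 1412 in ventral against cerebral organoids. Without a filter on low counts, which tests more genes, the counts were 1227 and 2298 in progenitor-like cells of dorsal and of ventral against cerebral organoids, 3955 in neuron-like cells of ventral against cerebral and 1328 in cortical glutamatergic neuron-like cells. With the hashtag number as a block, which pairs nothing here, 1408, 2089 and 3117 genes were called. With an estimated correlation 0, 0 and 1 gene lists passed. With a top hashtag of at least 80%, 2556 dorsal, 1781 ventral and 1071 cerebral cells were assigned.

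The GABAergic share of dorsal against ventral organoids passed at Leiden resolution 0.4 (-52.2 points) and 1.5 (-45.9), with the stricter cell filter (-44.1), with cells thinned before clustering (-45.9) and without dorsal organoid 2 (-55.8). The choroid plexus difference of dorsal against ventral organoids was 0.0349 points at resolution 1.5. Differences in other neurons were 6.08 points at resolution 1.5 and 1.99 after thinning in dorsal against cerebral organoids. After thinning the difference was 7.75 in ventral against cerebral organoids. At resolution 1.5 that class included a cluster of 643 dorsal cells led by SCG2 and LMO3. Its difference there does not describe Cajal-Retzius-like cells. The cortical glutamatergic difference of dorsal against cerebral organoids went from -7.17 to 6.56 when 1 organoid was left out, and was 1.36 without cerebral organoid 1. The number of shares past the threshold was 0 without any 1 ventral organoid or dorsal organoid 1, 3 or 4. It was 14 without any other organoid. Without dorsal organoid 1, 3 or 4 the lowest adjusted p of the lost calls was 0.05, equal to the threshold. Without 1 ventral organoid it was 0.0545 or more. The lost calls kept their direction and most of their size.

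Cycling differences without thinning were 0.803, -7.13 and -7.93 points in dorsal against ventral, dorsal against cerebral and ventral against cerebral organoids. With at least 1 marker they were 0.572 in dorsal against ventral and -3.87 in ventral against cerebral, and with at least 2 markers leaving out 1 organoid gave -2.50 to -0.984 in ventral against cerebral. The cortical marker difference of dorsal against cerebral organoids was 1.59 with at least 1 marker and -9.56 to 7.25 with 1 organoid left out, and that of dorsal against ventral 41.0 to 57.8. The GABAergic marker difference was -71.4 to -49.7 in dorsal against ventral and 7.76 to 29.4 in dorsal against cerebral organoids.

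The difference in spread was -0.0119 in dorsal against ventral and 0.0856 in ventral against cerebral organoids without thinning, and 0.0136 and -0.00445 with 1 minus the Spearman correlation, where both passed. With 1 organoid left out it was 0.0154 to 0.0998 in dorsal against ventral, 0.0210 to 0.105 in dorsal against cerebral and -0.00213 to 0.0161 in ventral against cerebral organoids.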

Other observations

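Cells of unnamed clusters were left out of the classes above. A cluster with high HSPA1A and DDIT3, genes of the stress response, held 6.39% of dorsal, 3.47% of ventral and 8.34% of cerebral cells. A cluster with LHX8, ISL1 and ZIC1, genes found together in cholinergic neurons of the ventral forebrain, held 8.65% of ventral cells against 0.443% of dorsal and 0.0713% of cerebral cells. A cluster with RAX and SIX6, factors of the early eye field and hypothalamus, held 4.31% of cerebral cells, with 139 of its 242 cells from organoid 2. A cluster with HOXB genes, which mark hindbrain and spinal cord, held 1.21% of cerebral cells. Neither of the last clusters had a cell in the dorsal or ventral library.

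POMC, a hormone precursor of hypothalamic neurons that was chosen after its values were seen, stood at 4.65, 0.151, 23.7 and 22.5 CPM in ventral organoids 1 to 4. Cells without a clear hashtag had a median of 5532 UMIs in the dorsal, 5095 in the ventral and 4106.5 in the cerebral library. In cells of the progenitor-like class, at least 2 cycling markers were found in 35.8% of dorsal, 51.5% of ventral and 47.0% of cerebral cells at 3000 UMIs.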
